A study of Bos taurus with 16 samples.

How the data were processed

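Affymetrix bovine GeneChip arrays were hybridised with RNA from cultured bovine theca interna cells in 4 groups: control, LH, BMP6 and LH+BMP6. Each group held 4 arrays, from 4 separate culture experiments on different batches of ovaries per the labels, which makes 16 arrays. The value table holds log2 signals, which per the submitters' processing notes the authors made with the robust multi-array average (RMA) method in Affymetrix Expression Console before they deposited them. The version of that software is not given in the sources used here. The table was used as deposited, with no further normalization, and 0 of its per-sample value columns were left unused.

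Of 24128 probe sets, 112 Affymetrix control probe sets were left out of the tests and 24016 were tested, with no filter on signal. GEO's platform annotation gave exactly 1 gene symbol to 13292 of the tested probe sets, several to 86 and none to 10638, which are unnamed here. Symbols were updated through Entrez identifiers, which were found for 13263 probe sets and changed 0 symbols, while 29 kept the symbol of the annotation. The named probe sets stand for 9155 genes. A gene's values are those of its probe set with the highest mean over the 16 arrays, and probe sets with several symbols were given no gene name. RXFP2, HSD3B2, SMAD6 and BMP6 are not named by the annotation used here, and GRO1 is its symbol for the listed gene CXCL1. No background level was estimated, so a signal of 3.50 or 4.49 is not said to be above or below background. Folds that end near the lower quartile of an array (4.31 to 4.43) or start at the top of its range are lower bounds. The precision comes from the replicate arrays, with a median SE of 0.102 for a difference between groups and 0.144 for the interaction.

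Probe sets were tested with limma 3.58.1 in R 4.3.3 on the log2 values: lmFit with a coefficient for each of the 4 groups over all 16 arrays, then eBayes with an intensity trend. The comparisons were LH against control, BMP6 against control, LH+BMP6 against LH, LH+BMP6 against BMP6, and the interaction of LH and BMP6. P values were adjusted by the Benjamini-Hochberg method over the 24016 probe sets, and a probe set is called at an adjusted p under 0.05. The adjusted p values of genes are those of limma. Errors of changes are limma's moderated standard errors. Quality measures were compared by exact permutation of the group labels and adjusted over 12 tests. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

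The design, the alternatives and 23 gene lists were fixed before the data were examined. The lists cover the steroidogenic pathway, theca hormones and their receptors, cholesterol synthesis and uptake, BMP-SMAD targets, BMP and activin genes, cAMP-responsive genes, insulin and IGF genes, collagens, matrix proteases, contractile genes, the cell cycle, osteogenic genes, the Wnt pathway, retinoid genes, glycolysis and hypoxia, the unfolded protein response, interferon-stimulated genes, and chemokines and inflammatory genes. Markers of endothelial cells, granulosa cells, leukocytes, pericytes and fibroblasts, and red blood cells make up the others. Lists were tested with camera of limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 115 tests, and again with the correlation estimated from the residuals. Of the lists called with the preset correlation, 0 were called with an estimated correlation. The count adjusted over the list alone uses the limma p values of the members of that list only.

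Genes were named by a fixed rule. It took the 12 largest rises and the 12 largest falls among called genes that changed the same way in 4 of 4 replicate numbers, up to 4 members of each list with the largest called change, and a fixed set of theca, granulosa and BMP genes. TM7SF2, DHCR7, SCARB1 and STC1 in LH against control, TSPO, GATA6 and DUSP1 in both tests of BMP6, and ALDOC and PTX3 in LH+BMP6 against LH were named after their values were seen, and SCG2, TF, RGN and LOC767968 were followed into other comparisons.

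The labels describe 4 experiments on different batches of ovaries, and the replicate numbers were taken to mark these experiments, which the labels do not state array by array. As a check, the deviations from the group means of arrays with the same number correlated across probe sets at a mean r of 0.16 for LH and control, 0.04 for BMP6 and control, 0.20 for LH+BMP6 and LH, and 0.38 for LH+BMP6 and BMP6. For arrays of different numbers the means were -0.05, -0.01, -0.07 and -0.12. For BMP6 and control the 4 values were 0.03, -0.11, 0.15 and 0.08, which shows no clear pairing. The main test has no replicate block, and the block was an alternative, as a fixed term and as a random effect (statmod 1.5.0). Further alternatives were eBayes without the trend or robust, dim probe sets left out (under the 40th percentile of mean signal), only the arrays compared, quantile normalization, arrays centred on their median, array weights, a single probe set per gene, a change of at least 1.5-fold, the mean of all probe sets of a gene, and each array and each replicate number left out in turn. Added after the data were seen were fits without the 3 arrays of low hybridisation-control signal or with that signal as a term, an estimated correlation together with the block, the fry test, and single arrays left out for the cholesterol and steroidogenic lists.

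The tests were tried on simulated data with shifts of 0.5, 1 and 2 on the log2 scale in 67, 67 and 66 of 24016 probe sets. In LH against control 74.6%, 94.0% and 100% of these were recovered, in BMP6 against control 53.7%, 97.0% and 100%, in LH+BMP6 against LH 59.7%, 98.5% and 100%, in LH+BMP6 against BMP6 67.2%, 97.0% and 100%, and in the interaction 26.9%, 85.1% and 98.5%. Unchanged probe sets made up 4.3%, 6.7%, 5.5%, 4.9% and 6.7% of the calls in the same order. Each comparison had a single draw of simulated data. The comparisons between groups have the same number of arrays, so their recoveries may differ by the draw alone. Recovery with another number of changed probe sets was not simulated. A list shifted by 0.5 was called in each of the 5 comparisons, with 0 of the 22 other lists called. The simulated genes varied independently, while the correlation estimated from the residuals was 0.796 for the cholesterol list. The simulation therefore could not show false list calls that come from correlated genes.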

Results

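Transcript levels were measured on Affymetrix bovine GeneChip arrays in theca interna cells, the androgen-producing cell layer of the ovarian follicle wall, taken from cattle ovaries and kept in serum-free primary culture for 6 days. From day 3 to day 6 the cultures received no hormone (control), luteinising hormone (LH, 160 pg/ml), bone morphogenetic protein 6 (BMP6, 10 ng/ml) or both together (LH+BMP6). Every group held 4 arrays, from 4 separate culture experiments on different batches of ovaries, so 16 arrays in all. Values are log2 signals of 24016 probe sets after 112 Affymetrix control probe sets had been set aside. Changes are given on the log2 scale ± SE with n = 4 arrays per group, and group levels as mean ± SD of 4 arrays. Every called gene named below changed in the same direction in 4 of 4 replicate numbers. The number of arrays limits the precision, and the median SE of a difference between groups was 0.102.

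The arrays with BMP6 lay apart from those without it on the leading principal component, which held 54.2% of the variance. On that component the 8 arrays with BMP6 scored between 20.0 and 32.5 and the 8 others between -43.8 and -15.0. Pairs of arrays of the same group correlated at r between 0.990 and 0.997 across probe sets, which are not independent replicates. In 3 arrays, all of them without BMP6 (control replicates 1 and 3 and LH replicate 1), the mean of the 9 hybridisation-control probe sets was 9.23 to 9.32, against 10.46 to 10.72 in the 13 others. Among the 8 arrays without BMP6 alone, with group as a term, 0 probe sets differed by limma between these 3 arrays and the rest. An unadjusted p under 0.05 was reached by 1506, and with the replicate block these counts were 0 and 840. The 3 prime minus 5 prime signal of the actin control, a sign of RNA quality, was 2.20 ± 0.35 in control, 2.10 ± 0.17 with LH, 1.85 ± 0.28 with BMP6 and 1.73 ± 0.28 with LH+BMP6. For BMP6 against control the exact two-sided permutation p was 0.171 (adjusted p = 0.41), and for LH+BMP6 against LH it was 0.0857 (adjusted p = 0.257), over a family of 12 tests. The same difference for GAPDH was 0.34 ± 0.05 in control and 0.23 ± 0.04 with BMP6 (exact p = 0.0286, the smallest that 4 against 4 arrays can give, adjusted p = 0.172).

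Few probe sets were called after LH alone. SCG2, which encodes the secretory granule protein secretogranin II, was 2.25-fold higher after LH, at 11.85 ± 0.13 against 10.68 ± 0.19 in control (1.17 ± 0.14, adjusted p = 0.00396, or 0.000878 with the replicate block). TF, the iron carrier transferrin, was 2.20-fold higher at 7.98 ± 0.35 against 6.85 ± 0.24 (1.13 ± 0.17, adjusted p = 0.0351, or 0.0751 with the replicate block). A probe set with no gene name in the annotation used here rose by 1.62 ± 0.23 (adjusted p = 0.025). These 3 probe sets were the only ones of 24016 called by limma, all of them higher, and 1291 had an unadjusted p under 0.05. RGN, regucalcin (2.39 ± 0.54, adjusted p = 0.509), and LOC767968, named in the annotation by a locus number alone (2.43 ± 0.43, adjusted p = 0.113), both followed after their values were seen, were not called. Without LH replicate 1 their differences were 1.66 and 1.89, and without LH replicate 3 LOC767968 was called (2.75, adjusted p = 0.0485). STAR and CYP17A1 spread widely. STAR, which carries cholesterol into mitochondria, differed by 1.49 ± 0.68 (adjusted p = 0.914) and CYP17A1, an enzyme of androgen synthesis, by 1.31 ± 0.52 (adjusted p = 0.898), and neither was called. INSL3, the peptide hormone of theca cells, stood at 14.07 ± 0.07 with LH and 14.08 ± 0.19 without (-0.01 ± 0.55, adjusted p = 0.998). Between 0 and 4 probe sets were brighter than INSL3 on each of these 8 arrays, so a rise of INSL3 with LH could not be read. CYP11A1 (0.50 ± 0.16, adjusted p = 0.74), HSD3B1 (0.28 ± 0.25, adjusted p = 0.941) and the LH receptor gene LHCGR (0.23 ± 0.19, adjusted p = 0.933) were not called either. STAR, CYP17A1, CYP11A1 and HSD3B1 had higher values with LH in 4 of 4 replicate numbers, and with the replicate block their adjusted p was 0.648, 0.542, 0.385 and 0.766. Without LH replicate 1 the differences were 0.98 for STAR, 0.59 for CYP17A1, 0.29 for CYP11A1 and 0.05 for HSD3B1. The TF call was lost without control replicate 1, 2 or 3 or without LH replicate 1, 2 or 4 (adjusted p between 0.0671 and 0.216), and without the 3 arrays of low hybridisation-control signal (0.85, adjusted p = 1.00). SCG2 kept its call without any single array, but lost it without those 3 arrays (0.95, adjusted p = 0.673), and 0 probe sets were then called.

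Cholesterol synthesis and uptake genes had higher values after LH as a list, with a median of 0.61 over 18 measured members. Of these, 0 were called over all probe sets and 14 rose and 0 fell when adjusted over the list alone. The list differed from other genes by camera (adjusted p = 8.33e-15, but adjusted p = 0.498 with an estimated correlation). TM7SF2 (1.43 ± 0.38, adjusted p = 0.622) and DHCR7 (0.86 ± 0.28, adjusted p = 0.74), both sterol reductases and both chosen after their values were seen, were among the members with large values. Without LH replicate 1 the difference was 0.51 for DHCR7, and without the 3 arrays of low hybridisation-control signal it was 0.76 for TM7SF2. The median was 0.38 without LH replicate 1, which is among the 3 arrays of low hybridisation-control signal, and 0.77 without LH replicate 4; it was 0.34 without the 3 arrays. The steroidogenic pathway list had a median of 0.21 over 16 members. Of these 0 were called over all probe sets, and 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 8.24e-06, but 0.498 with an estimated correlation). SCARB1, the receptor for lipoprotein cholesterol, chosen after its value was seen, was its member with the smallest adjusted p (0.73 ± 0.15, adjusted p = 0.377, or 0.46 without the 3 arrays). The median of this list was 0.11 without LH replicate 1. Glycolysis and hypoxia genes had a median of 0.17 over 20 members (adjusted p = 0.00351), cell cycle genes -0.18 over 30 (adjusted p = 0.000119) and contractile genes -0.13 over 14 (adjusted p = 0.0435), each with 0 members called either way, also adjusted over the list alone, and each at adjusted p = 0.825 with an estimated correlation. Interferon-stimulated genes had a median of -0.10 over 15 members (adjusted p = 0.0553, or 0.00948 with the replicate block, and adjusted p = 0.825 with an estimated correlation). The other 17 lists were not called, with adjusted p from 0.162 for matrix proteases to 0.954, and 0 of their members were called. Adjusted over the list alone, 1 of their members was, STC1 of the insulin and IGF list, chosen after its value was seen (-1.37 ± 0.29, adjusted p = 0.425 over all probe sets).

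**Figure D1:**
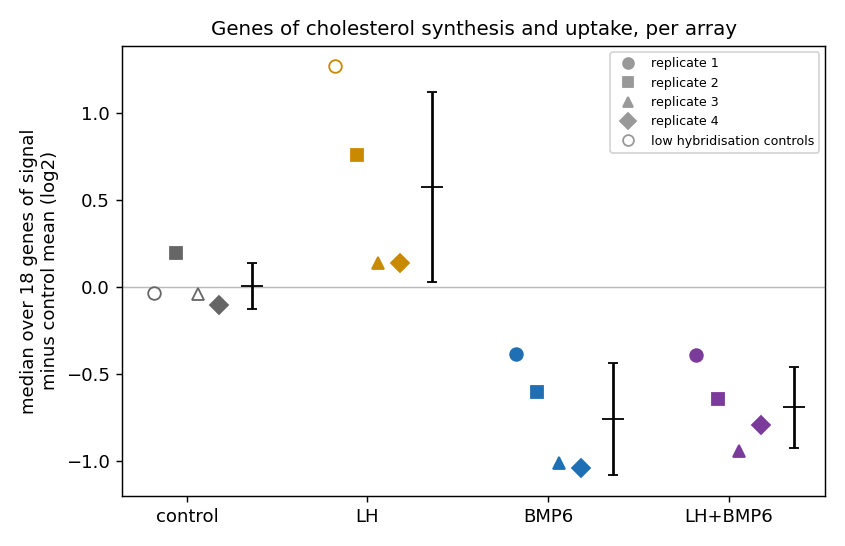
Median log2 level of the 18 cholesterol synthesis and uptake genes on each of the 16 arrays, relative to the control mean, by group, with a marker for each replicate number, the group mean as a black dash and the SD as a bar. Open symbols mark the 3 arrays of low hybridisation-control signal; LH replicates 1 and 2 stand at 1.27 and 0.76, LH replicates 3 and 4 both at 0.14, and all 8 arrays with BMP6 lie between -1.04 and -0.38.

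BMP6 lowered INSL3, INHA and several steroidogenic genes. INSL3 fell at least 52.0-fold, a lower bound because its signal without BMP6 lay at the top of the range, from 14.08 ± 0.19 in control to 8.38 ± 1.45 with BMP6 (-5.70 ± 0.55, adjusted p = 2.69e-06). INHA, the inhibin alpha subunit, fell 17.6-fold (-4.13 ± 0.24, adjusted p = 2.28e-08). CYP17A1 fell 6.96-fold from 7.38 ± 0.85 to 4.58 ± 0.33 (-2.80 ± 0.52, adjusted p = 0.00115), HSD3B1 5.04-fold (-2.33 ± 0.25, adjusted p = 8.96e-06) and CYP11A1, the enzyme of the opening step of steroid synthesis, 4.61-fold (-2.21 ± 0.16, adjusted p = 1.58e-07). LHCGR fell 4.18-fold (-2.06 ± 0.19, adjusted p = 1.33e-06) and NR5A1, a transcription factor that drives steroidogenic genes, 2.92-fold (-1.55 ± 0.10, adjusted p = 2.91e-08). STAR stood at 6.72 with BMP6 and 8.46 in control but spread too widely for a call (-1.74 ± 0.68, adjusted p = 0.0901). It was called without BMP6 replicate 3 (-2.23, adjusted p = 0.0371), and without all of replicate 3 in the fit with the replicate block (-2.31, adjusted p = 0.0377).

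In all, 4340 of 24016 probe sets (18.1%) were called by limma in BMP6 against control, 1950 of them higher and 2390 lower, and 264 rose and 244 fell by at least 2-fold. By gene, 852 of 9155 rose and 1422 fell. Other large falls included TNNI3, cardiac troponin I (-3.89 ± 0.28, 14.8-fold), NMB, neuromedin B (-3.08 ± 0.37), GPX3, a secreted glutathione peroxidase (-3.04 ± 0.46), EMID1 (-2.94 ± 0.18), STC1 (-2.74 ± 0.29), COL21A1 (-2.59 ± 0.08) and CELSR2 (-2.54 ± 0.23). COL21A1, a collagen gene, had the smallest adjusted p of the comparison (8.43e-13). Large rises included NOS2, inducible nitric oxide synthase (2.79 ± 0.41, 6.90-fold, adjusted p = 0.000155), ID1 (2.71 ± 0.20, 6.54-fold, adjusted p = 1.59e-07), UPK1B (2.61 ± 0.22), FOXO4 (2.45 ± 0.17), the MHC class II gene BOLA-DYA (2.38 ± 0.48), RSPO3, a secreted enhancer of Wnt signalling (2.14 ± 0.17), and ROR2, a Wnt receptor (2.11 ± 0.19). SLIT3 and IGSF10 rose by 2.07 ± 0.34 and 2.05 ± 0.39. The 3 prime minus 5 prime difference of actin was on average lower on the 8 arrays with BMP6 (-0.36 ± 0.14, with the arrays taken as independent). Without the 3 arrays of low hybridisation-control signal, 2 of them controls, 2660 probe sets were called. Without replicate 4 the count was 2703 and without replicate 3 it was 2821.

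**Figure D2:**
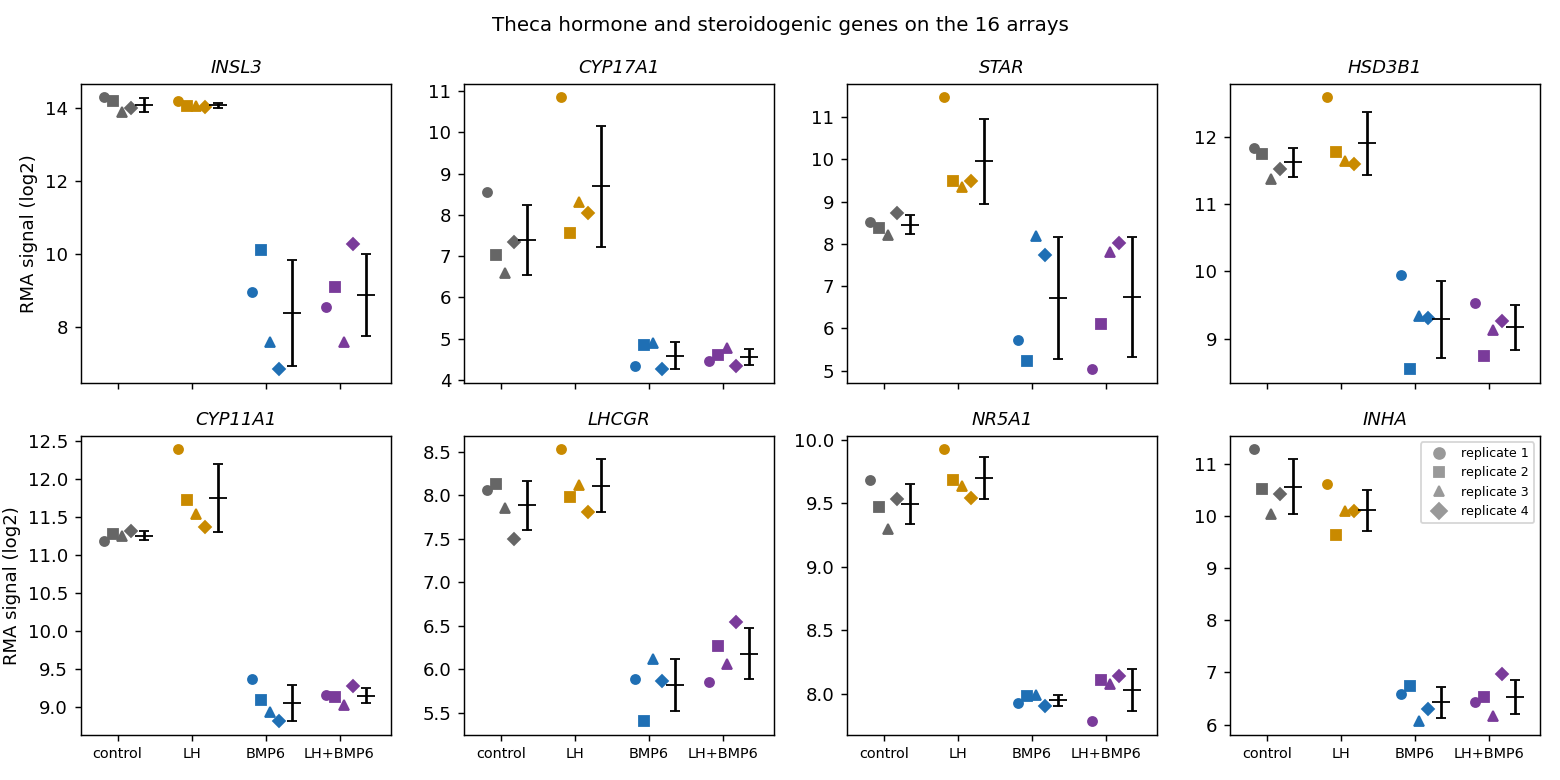
Log2 signal of theca genes on each of the 16 arrays by group, with a marker for each replicate number, the group mean as a black dash and the SD as a bar. INSL3 stands at 14.08 in control and 14.07 with LH, but at 8.38 with BMP6 and 8.88 with LH+BMP6; CYP17A1 stands at 7.38, 8.69, 4.58 and 4.54 in the same order.

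Of the 23 gene lists fixed in advance, 8 were called by camera in BMP6 against control and 0 of these 8 held with an estimated correlation. Direct targets of BMP-SMAD signalling had 5 of 9 measured members higher and 0 lower, also adjusted over the list alone (adjusted p = 2.28e-05, and adjusted p = 0.498 with an estimated correlation). They were ID1, ID2 (1.40 ± 0.18), ID3 (1.62 ± 0.18), TMEM100 (1.75 ± 0.29) and BAMBI (1.58 ± 0.13), a pseudoreceptor that dampens the pathway. In the steroidogenic list 2 of 16 members rose and 7 fell, or 2 and 10 adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.61 with an estimated correlation). The members that rose, both chosen after their values were seen, were TSPO, a protein of the outer mitochondrial membrane (0.88 ± 0.11, adjusted p = 5.25e-05), and the transcription factor gene GATA6 (0.38 ± 0.09, adjusted p = 0.00541). Genes of cholesterol synthesis and uptake had 0 of 18 members higher and 12 lower, or 0 and 14 adjusted over the list alone, with a median of -0.76 (adjusted p = 0.000157, and adjusted p = 0.825 with an estimated correlation). Their falls included the lanosterol synthase LSS (-1.35 ± 0.20, adjusted p = 0.000166) and TM7SF2 (-1.43 ± 0.38, adjusted p = 0.0129). The TM7SF2 call was lost with low hybridisation-control signal as a term (-1.13, adjusted p = 0.0913) and without replicate 2 or 4 (adjusted p = 0.0575 and 0.0596). SQLE also fell (-1.07 ± 0.29, adjusted p = 0.0163), a call lost without BMP6 replicate 4 (-0.94, adjusted p = 0.0595).

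Among glycolysis and hypoxia genes 15 of 20 rose and 0 fell, or 16 and 1 adjusted over the list alone (adjusted p = 2.13e-07, and adjusted p = 0.589 with an estimated correlation), with PFKFB3 up 4.63-fold (2.21 ± 0.34), BNIP3 2.89-fold (1.53 ± 0.26) and VEGFA 2.75-fold (1.46 ± 0.30). LDHA, lactate dehydrogenase A, rose 2.74-fold (1.46 ± 0.23), although 1 of its other probe sets was called in the opposite direction. Chemokines and inflammatory genes had 12 of 25 members higher and 0 lower, or 18 and 0 adjusted over the list alone (adjusted p = 1.95e-07, and adjusted p = 0.529 with an estimated correlation). PTGS2, the inducible prostaglandin synthase, rose 4.34-fold (2.12 ± 0.41), CCL20 3.67-fold (1.87 ± 0.35), IL6 3.14-fold (1.65 ± 0.39, adjusted p = 0.00693) and IL1B 2.55-fold (1.35 ± 0.21). Leukocyte markers had a median change of 0.28 with BMP6. Matrix proteases and inhibitors had 8 of 20 higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 2.43e-05, and adjusted p = 0.498 with an estimated correlation), led by the collagenase MMP1 (2.02 ± 0.23), ADAMTS1 (1.56 ± 0.18), the plasminogen activator PLAT (1.55 ± 0.21) and ADAMTS4 (1.45 ± 0.26). Of 14 cAMP-responsive genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.000181, and adjusted p = 0.498 with an estimated correlation). NR4A1 (1.16 ± 0.19), CREM (1.02 ± 0.19) and NR4A2 (0.97 ± 0.18) were among those that rose. The member that fell was DUSP1, a phosphatase chosen after its value was seen (-0.24 ± 0.07, adjusted p = 0.0327), a call lost without control replicate 1, 2 or 3 or any single BMP6 array (adjusted p between 0.0541 and 0.119). Wnt pathway genes had 7 of 16 members higher and 0 lower, or 9 and 1 adjusted over the list alone (adjusted p = 0.00046, and adjusted p = 0.498 with an estimated correlation), RSPO3, the secreted frizzled-related SFRP2 (1.45 ± 0.31) and DKK3 (1.08 ± 0.14) among them.

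**Figure D3:**
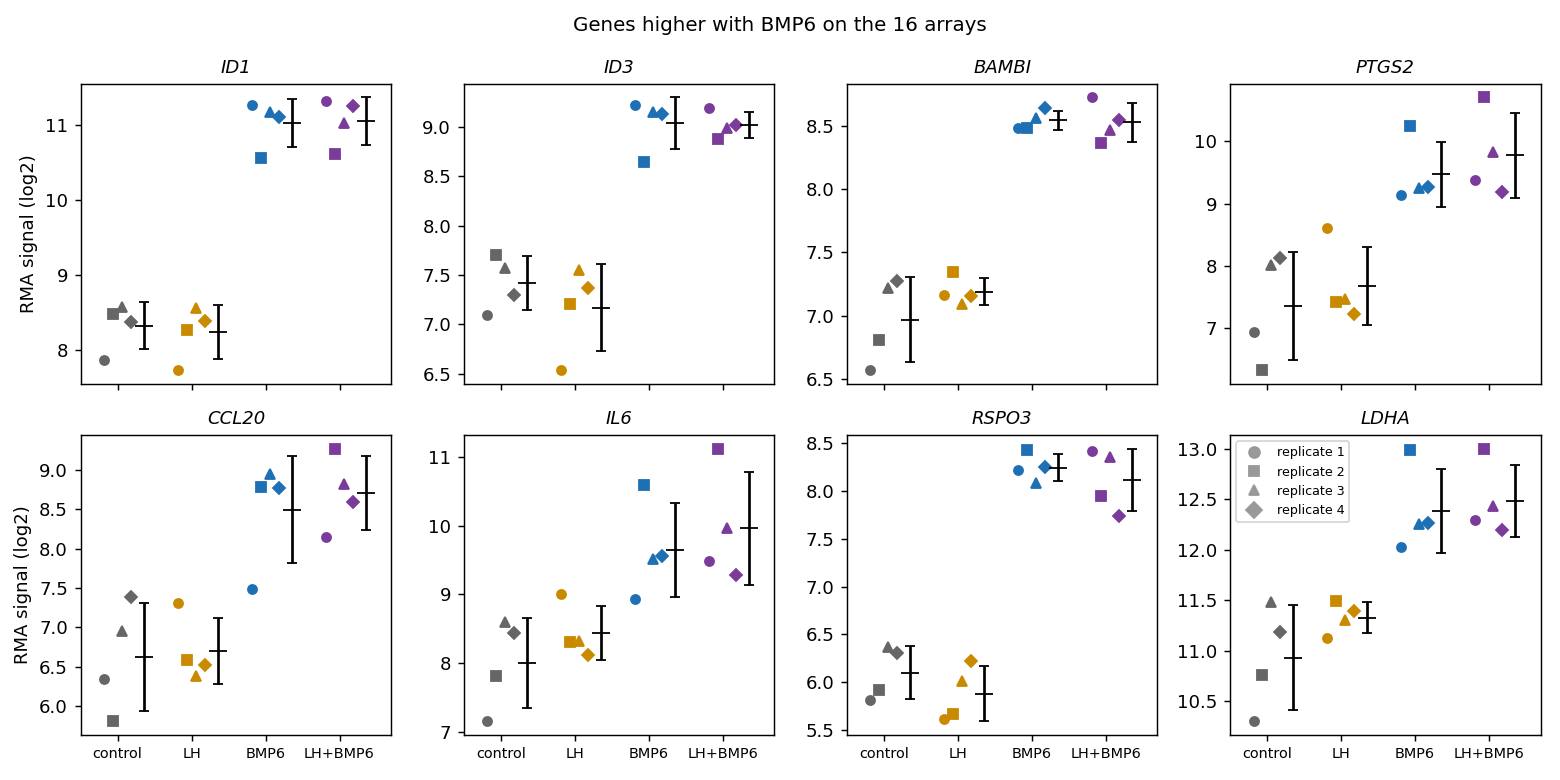
Log2 signal of genes that rose after BMP6 on each of the 16 arrays by group, with a marker for each replicate number, the group mean as a black dash and the SD as a bar. ID1 stands at 8.32 in control and 8.24 with LH, and at 11.03 with BMP6 and 11.06 with LH+BMP6.

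The other 15 lists were not called in BMP6 against control. Collagens and matrix proteins had 8 of 30 members higher and 3 lower, or 9 and 3 adjusted over the list alone (adjusted p = 0.0948, or 0.0484 with the replicate block, and adjusted p = 0.825 with an estimated correlation). VCAN and THBS2 rose by 1.51 ± 0.25 and 1.45 ± 0.21, while COL6A1 fell (-1.24 ± 0.15), as did OGN (-2.0 ± 0.52, adjusted p = 0.0117, or -2.64 without BMP6 replicate 1). In the list of theca hormones and their receptors 0 of 14 rose and 4 fell, or 1 and 4 adjusted over the list alone (adjusted p = 0.495). The 4 were INSL3, INHA, LHCGR and PRLR, the prolactin receptor gene. The PRLR call (-0.77 ± 0.22, adjusted p = 0.0186) was lost without control replicate 1 or 4 or BMP6 replicate 1 (adjusted p between 0.0525 and 0.0753). FST, follistatin, was not called (0.47 ± 0.22, adjusted p = 0.162, or 0.0447 with the replicate block). INHBA, the inhibin beta A subunit, was not called either (0.40 ± 0.15, adjusted p = 0.0666). Settings that did call INHBA were the replicate block (adjusted p = 0.0468, or 0.0488 as a random effect), low hybridisation-control signal as a term (0.52, adjusted p = 0.0404, or 0.0291 with the block), and leaving out control replicate 3 (0.52, adjusted p = 0.0173) or all of replicate 3 (0.56, adjusted p = 0.0337, or 0.0114 with the block). Of the insulin and IGF genes 3 of 14 rose and 3 fell, or 5 and 3 adjusted over the list alone (adjusted p = 0.399); STC1, INSR (-1.24 ± 0.22) and IGFBP4 (-1.0 ± 0.14) fell. BMP and activin ligands, receptors and SMADs had 5 of 25 higher and 2 lower, or 7 and 4 adjusted over the list alone (adjusted p = 0.162), with ENG, endoglin, higher (0.62 ± 0.16) and the receptor gene BMPR1B lower (-0.45 ± 0.11, adjusted p = 0.00757). The BMPR1B call was lost with the mean of its probe sets (-0.19, adjusted p = 0.0813). Among 10 retinoid genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.492), with RDH10 higher (1.20 ± 0.23) and ALDH1A1 (-1.54 ± 0.19) and DHRS3 (-1.41 ± 0.26) lower. Contractile genes had 3 of 14 higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.118), DES among them (0.76 ± 0.15). Cell cycle genes had 2 of 30 higher and 1 lower, or 1 and 0 adjusted over the list alone (adjusted p = 0.139), TK1 being higher (0.76 ± 0.18, adjusted p = 0.00568). Of 15 osteogenic and chondrogenic genes ALPL alone was called (1.10 ± 0.23, adjusted p = 0.00288), and it alone adjusted over the list alone (list adjusted p = 0.396). Unfolded protein response genes had 2 of 18 higher, or 1 adjusted over the list alone, and 0 lower (adjusted p = 0.475), with HMOX1, heme oxygenase, higher (0.67 ± 0.09). Interferon-stimulated genes had 0 of 15 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.821), PSMB9 being lower (-0.36 ± 0.09, adjusted p = 0.00973).

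Of the 5 lists of markers of other cell types, 0 were called in BMP6 against control. Of 14 leukocyte markers 1 rose, also adjusted over the list alone, and 0 fell, with a median of 0.28 (adjusted p = 0.0553, or 0.0175 and 5 members higher with the replicate block, and adjusted p = 0.825 with an estimated correlation). The called marker was CD14, of monocytes (1.13 ± 0.24, adjusted p = 0.00286). Of 13 endothelial markers 0 rose and 1 fell, 0 adjusted over the list alone, with a median of -0.12 (adjusted p = 0.78). It was the tight-junction gene CLDN5 (-0.88 ± 0.27, adjusted p = 0.0316), a call lost without control replicate 3 or 4 or BMP6 replicate 1 or 2 (adjusted p between 0.0602 and 0.104). Of 13 granulosa cell markers 2 rose and 1 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.517): CDH2 (1.67 ± 0.27) and SERPINE2 (0.92 ± 0.12) were higher and INHA was lower. The granulosa genes FSHR, at 3.50 in control, and CYP19A1, at 4.49, were not called (adjusted p = 0.712 and 0.363). Pericyte and fibroblast markers had 4 of 14 higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.0695), with DCN (0.73 ± 0.16) and TCF21 (0.67 ± 0.09) among them. Of 6 red blood cell genes 0 were called, also adjusted over the list alone (adjusted p = 0.495).

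In LH-stimulated cells BMP6 again lowered INSL3, INHA and several steroidogenic genes. INSL3 fell at least 36.6-fold from 14.07 ± 0.07 with LH to 8.88 ± 1.12 with LH+BMP6 (-5.20 ± 0.55, adjusted p = 6.31e-06). CYP17A1 fell from 8.69 ± 1.47 to 4.54 ± 0.20 (-4.15 ± 0.52, adjusted p = 3.37e-05), or -3.43 without LH replicate 1. INHA fell 11.9-fold (-3.58 ± 0.24, adjusted p = 7.15e-08) and STAR 9.25-fold (-3.21 ± 0.68, adjusted p = 0.00264). The STAR signal was 11.47 on LH replicate 1 and 9.34 to 9.49 on the other LH arrays, so the size of its fall rests in part on that array. HSD3B1 (-2.73 ± 0.25), CYP11A1 (-2.61 ± 0.16), LHCGR (-1.93 ± 0.19) and NR5A1 (-1.67 ± 0.10) fell as well. Other large falls included those of TNNI3 (-3.97 ± 0.28), NMB (-3.77 ± 0.37), NUDT11 (-3.56 ± 0.50), RGN (-3.42 ± 0.54, or -2.69 without LH replicate 1), GPX3 (-2.87 ± 0.46) and LOC767968 (-4.75 ± 0.43). LOC767968 lay under the lower quartile of the array in 4 of 4 LH+BMP6 arrays, so its fall is a lower bound. Part of these 2 falls starts from higher values with LH than in control. Without LH, RGN was not called after BMP6 (-0.81 ± 0.54, adjusted p = 0.358, or 0.00235 with only the arrays compared) and LOC767968 fell (-2.48 ± 0.43, adjusted p = 0.000627). Their interactions were -2.61 ± 0.77 and -2.27 ± 0.61 (adjusted p = 1.00 for both). LOC767968 lay under the lower quartile in 4 of 4 BMP6 arrays as well, so its interaction is not an exact difference of the 2 falls. Large rises included those of UPK1B (3.10 ± 0.22, 8.57-fold), BOLA-DYA (3.02 ± 0.48), ID1 (2.82 ± 0.20, 7.06-fold), NOS2 (2.59 ± 0.41), FBXO32, a ubiquitin ligase subunit (2.48 ± 0.28), FOXO4 (2.37 ± 0.17), IGSF10 (2.35 ± 0.39), ANXA8L1 (2.25 ± 0.31), RSPO3 (2.23 ± 0.17) and SLIT3 (2.16 ± 0.34). In all, 4879 of 24016 probe sets (20.3%) were called by limma, 2399 higher and 2480 lower, and 358 rose and 276 fell by at least 2-fold. By gene, 1074 of 9155 rose and 1418 fell. Without replicate 3 the count was 2963.

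In LH+BMP6 against LH, 12 of the 23 lists were called by camera, and 0 of them with an estimated correlation. Cholesterol synthesis and uptake genes had 0 of 18 members higher and 17 lower, also adjusted over the list alone, with a median of -1.28 (adjusted p = 1.22e-08, and adjusted p = 0.589 with an estimated correlation). TM7SF2 (-2.76 ± 0.38, 6.77-fold), DHCR7 (-1.73 ± 0.28) and CYP51A1 (-1.67 ± 0.28) were among them. The steroidogenic list had 2 of 16 higher and 9 lower, or 2 and 11 adjusted over the list alone (adjusted p = 0.000675, and adjusted p = 0.529 with an estimated correlation). TSPO (1.10 ± 0.11, adjusted p = 5.66e-06) and GATA6 (0.32 ± 0.09, adjusted p = 0.0152), both chosen after their values were seen, were its higher members, and GATA6 lost its call without LH replicate 4 (0.26, adjusted p = 0.0557) or LH+BMP6 replicate 1 (0.25, adjusted p = 0.0558). BMP-SMAD targets had 5 of 9 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.000119, and adjusted p = 0.498 with an estimated correlation), ID2 (1.66 ± 0.18), ID3 (1.85 ± 0.18) and TMEM100 (1.72 ± 0.29) among them. Glycolysis and hypoxia genes had 16 of 20 higher and 1 lower, also adjusted over the list alone (adjusted p = 7.79e-07, and adjusted p = 0.589 with an estimated correlation). PFKFB3 (1.97 ± 0.34), VEGFA (1.34 ± 0.30) and BNIP3 (1.25 ± 0.26) rose. ALDOC, an aldolase chosen after its value was seen, fell (-0.49 ± 0.14, adjusted p = 0.0154), a call lost without LH replicate 1 (adjusted p = 0.0552) or LH+BMP6 replicate 3 (adjusted p = 0.0528). Chemokines and inflammatory genes had 17 of 25 higher and 1 lower, or 18 and 1 adjusted over the list alone (adjusted p = 1.91e-08, and adjusted p = 0.498 with an estimated correlation). PTGS2 (2.09 ± 0.41), CCL20 (2.01 ± 0.35) and GRO1, the chemokine CXCL1 (1.41 ± 0.20), rose. PTX3, pentraxin 3, chosen after its value was seen, fell (-1.34 ± 0.42, adjusted p = 0.0295), a call lost without LH replicate 1 or 2 or any single LH+BMP6 array (adjusted p between 0.0515 and 0.0965).

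Matrix proteases and inhibitors had 9 of 20 higher and 0 lower in LH+BMP6 against LH, or 9 and 1 adjusted over the list alone (adjusted p = 0.000123, and adjusted p = 0.529 with an estimated correlation), with MMP1 (1.73 ± 0.23) and PLAT (1.49 ± 0.21) higher. Of 14 cAMP-responsive genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (adjusted p = 0.000198, and adjusted p = 0.498 with an estimated correlation), with NR4A1 (1.58 ± 0.19) and NR4A2 (1.21 ± 0.18) higher. DUSP1 was again the member that fell (-0.21 ± 0.07, adjusted p = 0.0486, or 0.0507 with the replicate block), and its call was lost without LH replicate 1, 3 or 4 or LH+BMP6 replicate 1, 2 or 4 (adjusted p between 0.0571 and 0.163). Wnt genes had 6 of 16 higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.00331, and adjusted p = 0.548 with an estimated correlation), with SFRP2 (1.66 ± 0.31) and DKK3 (1.20 ± 0.14) among them. Leukocyte markers had 8 of 14 higher and 0 lower, also adjusted over the list alone, with a median of 0.57 (adjusted p = 0.00331, and adjusted p = 0.61 with an estimated correlation). CD14 (1.04 ± 0.24, adjusted p = 0.00462) and the T cell gene CD3E (0.91 ± 0.23, adjusted p = 0.00922) rose, as did PTPRC, the pan-leukocyte CD45 (0.95 ± 0.26, adjusted p = 0.0161), a call lost without LH+BMP6 replicate 2 (0.86, adjusted p = 0.0505) and without the arrays of low hybridisation-control signal (0.60, adjusted p = 0.0516). Without LH replicate 1, which is among these arrays, the rise of PTPRC was 0.60 (adjusted p = 0.0348). CD3E too was low on that array, at 6.72 against 7.70 to 7.94 on the other LH arrays. CD3D, another of the 8 called markers, lost its call without LH replicate 1 (0.61, adjusted p = 0.0618) or LH+BMP6 replicate 2 (0.74, adjusted p = 0.06). Cell cycle genes had 2 of 30 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0051, and adjusted p = 0.825 with an estimated correlation), TK1 (1.09 ± 0.18) and MCM6 (0.46 ± 0.12, adjusted p = 0.00996). Contractile genes had 5 of 14 higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.00619, and adjusted p = 0.825 with an estimated correlation), among them DES (0.87 ± 0.15). TAGLN also rose (0.80 ± 0.22, adjusted p = 0.0133), a call lost without LH replicate 1 (0.69, adjusted p = 0.051), and without all of replicate 1 (0.62, adjusted p = 0.0827) or replicate 4 (0.74, adjusted p = 0.0977). Collagens and matrix proteins had 9 of 30 higher and 4 lower, or 10 and 4 adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.825 with an estimated correlation), with VCAN higher (1.77 ± 0.25) and COL6A1 lower (-1.11 ± 0.15).

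**Figure D4:**
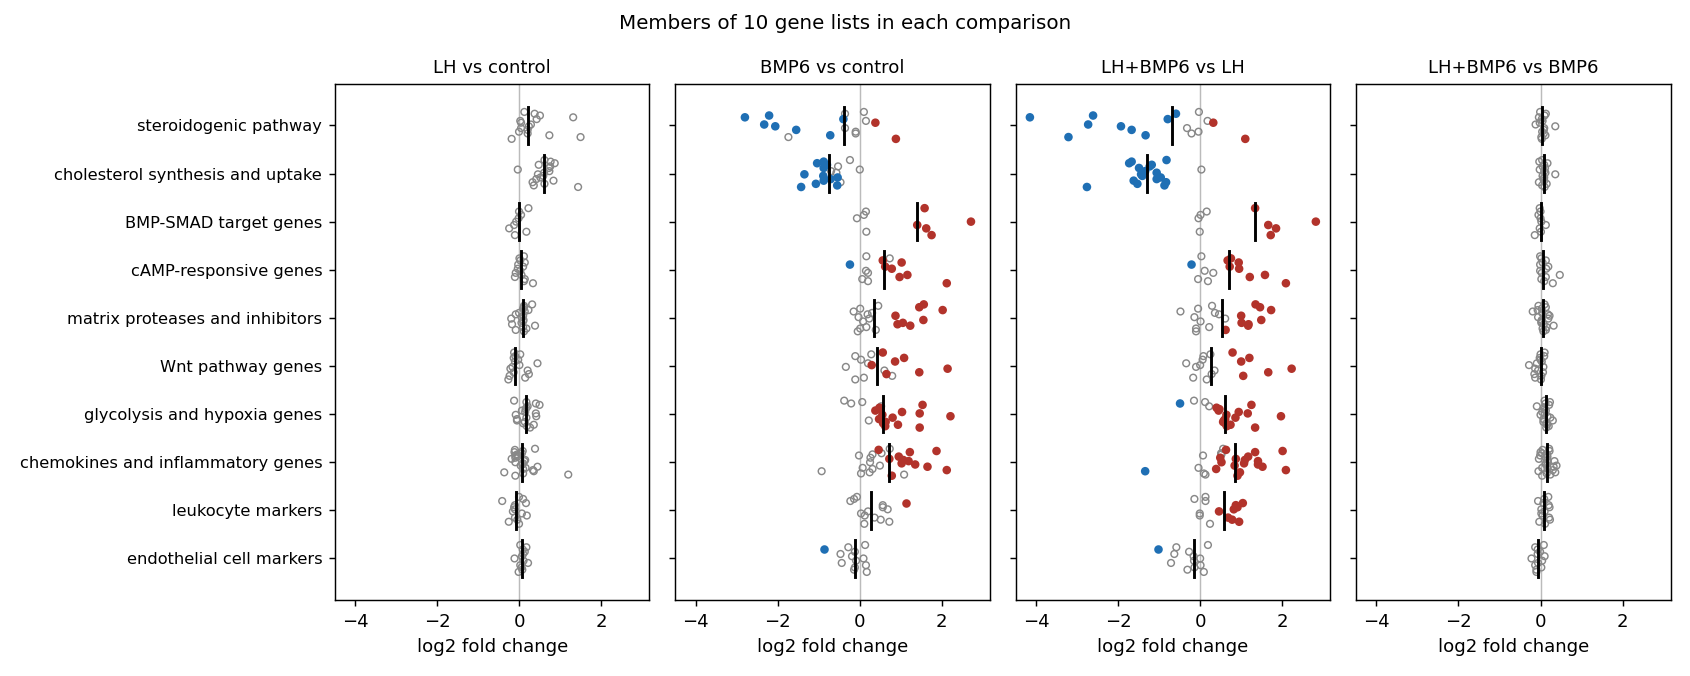
Log2 change of every measured member of 10 gene lists in 4 comparisons, each point a gene; filled red and blue points were called higher and lower at an adjusted p under 0.05, open points were not called, and the black line is the list median. The medians of the cholesterol list are 0.61 for LH against control, -0.76 for BMP6 against control, -1.28 for LH+BMP6 against LH and 0.09 for LH+BMP6 against BMP6.

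The other 11 lists were not called in LH+BMP6 against LH. Theca hormones and their receptors had 2 of 14 members higher and 3 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.495); INSL3, INHA and LHCGR were lower. INHBA rose (0.45 ± 0.15, adjusted p = 0.0347), a call lost without LH replicate 2 or 3 or LH+BMP6 replicate 1, 2 or 4 (adjusted p between 0.0694 and 0.111). FST rose too (0.68 ± 0.22, adjusted p = 0.0353), a call lost without LH replicate 1, 3 or 4 or LH+BMP6 replicate 1, 2 or 3 (adjusted p between 0.0602 and 0.125). BMP and activin genes had 3 of 25 higher and 1 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.319), with ENG higher (0.62 ± 0.16) and BMPR1B lower (-0.48 ± 0.11). Insulin and IGF genes had 5 of 14 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.59), with IGFBP3 higher (0.89 ± 0.22) and INSR lower (-1.12 ± 0.22). Retinoid genes had 4 of 10 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.245), ALDH1A1 being lower (-1.88 ± 0.19). Osteogenic and chondrogenic genes had 2 of 15 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.445), with ALPL higher (1.37 ± 0.23). Unfolded protein response genes had 2 of 18 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.475), with HMOX1 higher (0.67 ± 0.09). Interferon-stimulated genes had 2 of 15 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.708). The lower member was PSMB9 (-0.30 ± 0.09, adjusted p = 0.0271), a call lost without LH replicate 2 or LH+BMP6 replicate 3 or 4 (adjusted p between 0.0636 and 0.0908). Endothelial markers had 0 of 13 higher and 1 lower, CLDN5 (-1.03 ± 0.27, adjusted p = 0.0115), also adjusted over the list alone, with a list median of -0.16 (adjusted p = 0.37). Granulosa markers had 2 of 13 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.954), with CDH2 (1.77 ± 0.27) and SERPINE2 (1.18 ± 0.12) higher. Pericyte and fibroblast markers had 3 of 14 higher and 3 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.384), with TCF21 (0.77 ± 0.09) and DCN (0.74 ± 0.16) higher. Of 6 red blood cell genes 0 were called, also adjusted over the list alone (adjusted p = 0.821).

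The BMP6 responses with and without LH, which share no array, overlapped. The probe sets called higher in both numbered 1532, 78.6% of the 1950 without LH, and those called lower in both 1728, 72.3% of 2390. Independent lists of these sizes would share 194.8 and 246.8. A total of 0 probe sets were called in opposite directions, where independent lists would share 201.4 and 238.7. Across all 24016 probe sets the log2 changes correlated at r = 0.90 (covariance 0.1149), and at 0.95 over the 5959 called in either comparison. These are correlations across probe sets, which are not independent replicates. The LH and BMP6 effects, both measured against the same control arrays, correlated at 0.06 (covariance 0.0028), where unchanged groups simulated against those controls gave 0.50 (covariance 0.0085). With the controls split between both effects the mean correlation over 6 splits was -0.06 (covariance -0.0044; range -0.35 to 0.21).

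With BMP6 present no theca gene that was followed was called after LH, at errors that leave changes of over 1 open for INSL3, CYP17A1 and STAR. INSL3 stood at 8.88 ± 1.12 with LH+BMP6 and 8.38 ± 1.45 with BMP6 (0.50 ± 0.55), LHCGR at 6.18 and 5.82 (0.36 ± 0.19), CYP17A1 at 4.54 and 4.58 (-0.04 ± 0.52) and STAR at 6.74 and 6.72 (0.02 ± 0.68), each with an adjusted p of 1.00. CYP17A1 lay at 4.26 to 4.89 with BMP6 and 4.32 to 4.78 with LH+BMP6, near the lower quartile of the array (4.33 to 4.41). A change of CYP17A1 with LH could therefore not be read well here. The INSL3 difference was 0.03 without LH+BMP6 replicate 4, -0.01 without BMP6 replicate 4 and 1.07 without BMP6 replicate 2, and that of STAR lay between -0.47 and 0.59 with a single array left out. SCG2 and TF, the genes that rose after LH alone, differed by 0.34 ± 0.14 and 0.13 ± 0.17 (adjusted p = 1.00 for both). Limma called 0 of 24016 probe sets in LH+BMP6 against BMP6, 471 had an unadjusted p under 0.05, and with the replicate block the counts were 0 and 631. As lists, chemokines and inflammatory genes had a median of 0.16 (adjusted p = 0.00172) and glycolysis and hypoxia genes of 0.13 (adjusted p = 0.00455), each at adjusted p = 0.825 with an estimated correlation and with 0 members called, also adjusted over the list alone. The GAPDH 3 prime minus 5 prime difference was 0.14 ± 0.02 with LH+BMP6 and 0.23 ± 0.04 with BMP6 (exact p = 0.0286, the smallest possible, adjusted p = 0.172). With the replicate block matrix proteases and leukocyte markers also passed, both at adjusted p = 0.0484, against 0.223 and 0.118 without it; both stood at adjusted p = 0.825 with an estimated correlation. The cholesterol list had a median of 0.09 (adjusted p = 0.384). For the other 18 lists the adjusted p ranged from 0.118 to 0.954, with 0 members called, also adjusted over the list alone.

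Whether the BMP6 effect differed between LH-stimulated and basal cells was tested as an interaction. The log2 fall of CYP17A1 with BMP6 was larger in LH-stimulated cells by an estimate that was not called (-1.35 ± 0.74), as were those of STAR (-1.47 ± 0.96) and CYP11A1 (-0.40 ± 0.23), each with an adjusted p of 1.00. Without LH replicate 1 these estimates were -0.63 for CYP17A1, -0.96 for STAR and -0.19 for CYP11A1, and without the 3 arrays of low hybridisation-control signal -0.82, -0.88 and -0.15. The STAR estimate was -0.90 without LH+BMP6 replicate 1. CYP17A1 lay at 4.26 to 4.89 with BMP6 and 4.32 to 4.78 with LH+BMP6, near the lower quartile of the array (4.33 to 4.41). Both of its falls are therefore lower bounds, and its interaction is not an exact difference of the BMP6 effects. For SCG2 (-0.83 ± 0.20) and TF (-1.0 ± 0.24), the genes called after LH alone, the adjusted p was also 1.00, so a difference of the LH response with BMP6 was not shown. BMP6 alone raised SCG2 (0.74 ± 0.14, adjusted p = 0.00117) and lowered TF (-0.74 ± 0.17, adjusted p = 0.0057). Limma called 0 probe sets, 773 had an unadjusted p under 0.05, and with the replicate block the counts were 0 and 1022. The median SE of the interaction was 0.144. As lists, cholesterol synthesis and uptake genes had a median interaction of -0.51 (adjusted p = 1.22e-08), the steroidogenic pathway -0.13 (adjusted p = 0.00573) and cell cycle genes 0.15 (adjusted p = 0.0492), with adjusted p = 0.589, 0.589 and 0.825 with an estimated correlation. In these lists 0 members were called, also adjusted over the list alone. With the replicate block endothelial (-0.15), leukocyte (0.22) and pericyte markers (-0.12) also passed, at adjusted p = 0.0484, 0.0484 and 0.0462, against 0.162, 0.0959 and 0.118 without it and 0.825 each with an estimated correlation. For the other 17 lists the adjusted p ranged from 0.0712 to 0.954, with 0 members called, also adjusted over the list alone. Without the 3 arrays of low hybridisation-control signal the cholesterol median was -0.25 (adjusted p = 0.0024) and the steroidogenic one -0.09 (adjusted p = 0.125).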

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

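The tests of the LH response removed by BMP6, of INSL3 against NR5A1, of the actin control and of the leukocyte and endothelial markers were chosen only after the results were seen. For the tests without LH replicate 1 and without the arrays of low hybridisation-control signal, the predictions were written before the results of these tests. Both tests were nevertheless added after the data were seen, so they were not fixed in advance.

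In 98 genes over 392 groups of 4 arrays, 26 groups (6.6%) held an array whose gap to the nearest of the others exceeded 0.829 of the range of the group, Dixon's limit. Chance flags about 1 in 20 groups. Of 12 groups of quality measures 1 was so marked: the hybridisation controls averaged 9.27 on LH replicate 1, against 10.50 to 10.72 on the other LH arrays. LH replicate 1 stood apart in 8 groups, that one included. Its STAR signal was 11.47 (9.34 to 9.49 on the other 3 LH arrays), CELSR2 7.87 (7.08 to 7.20), SLIT3 6.27 (6.9 to 7.0), ADAMTS4 9.16 (9.27 to 9.29), IGFBP3 9.82 (10.33 to 10.36), ANXA8L1 4.87 (5.95 to 6.05) and MCM6 8.40 (8.79 to 8.85). BMP6 replicate 1 stood apart in 6 groups, GPX3 at 4.98 (4.23 to 4.34 on the other 3 BMP6 arrays), GATA6 at 11.53 (11.34 on all 3), LSS at 8.28 (7.54 to 7.61), CCL20 at 7.49 (8.77 to 8.95), IL1B at 6.67 (7.47 to 7.48) and OGN at 9.71 (7.10 to 7.17). BMP6 replicate 2 stood apart in 6 as well, ID3 at 8.65 (9.13 to 9.22), PFKFB3 at 9.82 (8.80 to 8.85), PTGS2 at 10.24 (9.13 to 9.26), RDH10 at 9.24 (8.35 to 8.44), DES at 7.80 (7.31 to 7.34) and DUSP1 at 8.93 (9.01 to 9.02). In control replicate 1 the signals of SFRP2 (6.5, others 7.26 to 7.38) and THBS2 (9.29, others 10.42 to 10.57) were far below the others. The remaining 5 were CELSR2 on BMP6 replicate 4 (4.43, others 4.90 to 5.00), TSPO on LH+BMP6 replicate 2 (11.11, others 10.75 to 10.81), SQLE on LH+BMP6 replicate 1 (9.98, others 9.12 to 9.23), IGFBP4 on LH replicate 3 (11.13, others 10.87 to 10.90) and DCN on LH+BMP6 replicate 4 (13.38, others 13.66 to 13.69).

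In 3 lists the interaction of LH and BMP6 was called by camera with the preset inter-gene correlation of 0.01. The medians were -0.51 for cholesterol synthesis and uptake (adjusted p = 1.22e-08), -0.13 for the steroidogenic pathway (adjusted p = 0.00573) and 0.15 for cell cycle genes (adjusted p = 0.0492). With an estimated correlation (0.796, 0.189 and 0.53) the adjusted p values were 0.589, 0.589 and 0.825. The fry test called 0 lists in the interaction, so a difference of the BMP6 effect between LH-stimulated and basal cells was not established.

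The higher cholesterol genes after LH alone could come from a single culture or from the arrays of low hybridisation-control signal rather than from LH. Without LH replicate 1 the median was 0.38 ± 0.22 and without the 3 low-signal arrays 0.34 ± 0.26, so both explanations stay open. By replicate number the LH change was 1.46, 0.56, 0.18 and 0.25 without BMP6, and 0.05, -0.03, 0.02 and 0.19 with it. It was lower with BMP6 in 4 of 4 numbers and by over 0.2 in 2. In replicate 3 the 0.18 left little room for a drop of over 0.2. In replicate 4 there was room, but the LH change was lower with BMP6 by only 0.06. The test therefore does not decide, and a response to LH that BMP6 removes was not shown in every replicate number and stays open too.

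The lower INSL3 and steroidogenic genes after BMP6 might reflect fewer theca cells or poorer RNA instead of lower expression per cell. Over both LH conditions INSL3 changed by -5.45 ± 0.46 and NR5A1 by -1.61 ± 0.07, a difference of -3.84 ± 0.45. A ceiling on INSL3 could only make this difference too small, but a compressed NR5A1 signal could make it too large. The difference argues against fewer theca cells as the sole cause only under conditions that were not tested. Theca cells alone must make both transcripts, and both probe sets must follow RNA levels alike. The actin 3 prime minus 5 prime difference was on average lower, not higher, on the arrays with BMP6 (-0.36 ± 0.14), so this control gave no sign of poorer RNA on average. Its SE takes the arrays as independent. In replicate 1 the value was higher with BMP6 (2.21) than in control (1.69), and equal with LH+BMP6 and LH (1.91), so poorer RNA in that replicate stays open. A smaller share of theca cells as part of the cause was not tested.

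The higher chemokine and inflammatory genes after BMP6 might reflect a larger share of leukocytes, or fewer theca cells, which would raise every other cell type alike. Averaged over both LH conditions, the median BMP6 change of the 17 inflammatory genes called higher in either condition had a mean of 0.97 ± 0.14 over 4 replicate numbers, and that of 10 leukocyte markers above the median signal 0.66 ± 0.05. The difference was 0.31 ± 0.10 (95% interval 0.00 to 0.63), and 0.20 ± 0.10 (-0.10 to 0.51) with all inflammatory genes above the median signal, so a larger share of leukocytes stays open. Leukocyte minus endothelial markers came to 0.59 ± 0.10 (0.28 to 0.91), positive in 4 of 4 replicate numbers. This argues against a loss of theca cells as the sole cause, if it would raise these cell types alike. Pericyte and fibroblast markers were not part of this test, and a smaller share of theca cells as part of the cause was not tested.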

How the results depend on the processing

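The fits without the arrays of low hybridisation-control signal, or with that signal as a term, were chosen only after the data were seen. Of 93 called genes named in BMP6 against control, 71 kept their call under all alternatives, and of 100 in LH+BMP6 against LH, 70 did. Of the 2 named in LH against control, 0 did: SCG2 lost its call without replicate 1 (1.06, adjusted p = 0.191), 3 (1.13, adjusted p = 0.216) or 4 (1.24, adjusted p = 0.0508). Of 6 uncalled genes named in BMP6 against control 4 gained a call under some alternative, RGN (-0.81, adjusted p = 0.00235) with only the arrays compared. In LH against control LOC767968 gained its call without LH replicate 3 (2.75, adjusted p = 0.0485). IBSP alone turned direction: in LH+BMP6 against LH it changed by -0.15 ± 0.05 (adjusted p = 0.0429), but by 0.29 (adjusted p = 0.229) with the mean of all probe sets of the gene. The cause was not tested. Without a replicate number, TM7SF2, SQLE, DHCR7, ENG, BMPR1B, OGN, TK1, PSMB9, CLDN5, PRLR and DUSP1 lost their calls in BMP6 against control, and IL6, CD14, CD3E, PTPRC, CLDN5, ENG, BMPR1B, IGFBP3, TAGLN, ALDOC, PTX3, GATA6, PSMB9, INHBA, FST and DUSP1 in LH+BMP6 against LH, each for at least 1 number. With the mean of all probe sets NOS2 (1.58), ID1 (1.39), PFKFB3 (0.87), EMID1 (-1.53), CELSR2 (-1.46), LHCGR (-1.35), LDHA (0.38), CREM (0.26), NR4A2 (0.29), INSR (-0.54), COL6A1 (-0.64), LSS (-0.77), TMEM100 (1.01) and NR5A1 (-0.92) kept their calls in BMP6 against control at changes over 1.5 times smaller. In LH+BMP6 against LH this held for ID1 (1.42), NOS2 (1.45), RGN (-1.65), TMEM100 (0.84), BMPR1B (-0.27), NR4A2 (0.32), INSR (-0.53), PFKFB3 (0.85) and NR5A1 (-0.92). The IBSP call was also lost without LH replicate 1, 3 or 4 or any single LH+BMP6 array.

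Counts of called probe sets moved over 1.5 times in some settings. Fewer arrays, fewer probe sets or a stricter limit entered most of these, and for low signal as a term the cause was not tested. In LH against control the 3 calls became 1 with only the arrays compared, 0 without the 3 arrays of low hybridisation-control signal, and between 0 (without replicate 1, 3 or 4) and 6 (without LH replicate 3) in the fits that leave out arrays. In BMP6 against control the 4340 calls became 2544 with a single probe set per gene (961 higher and 1583 lower), 1609 with at least a 1.5-fold change (868 higher and 741 lower), 2660 without the 3 arrays, 2766 with low signal as a term, and between 2703 (without replicate 4) and 4054 (without replicate 1, replicate block) in the fits that leave out arrays. In LH+BMP6 against LH the 4879 calls became 2765 with a single probe set per gene (1179 higher and 1586 lower), 1950 with at least a 1.5-fold change (1164 higher and 786 lower), and between 2963 (without replicate 3) and 5194 (without replicate 2, replicate block). LH+BMP6 against BMP6 and the interaction stayed at 0 in every setting.

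With the replicate block the counts were 2, 5202, 5706, 0 and 0 for LH against control, BMP6 against control, LH+BMP6 against LH, LH+BMP6 against BMP6 and the interaction, and the probe sets changed alike by BMP6 with and without LH went from 3260 to 3996. The block as a random effect gave 3, 4970, 5565, 0 and 0, and the block with low signal as a term 3, 3825, 5230, 0 and 0. Besides the values given beside their results, the block changed no call of a gene named here. Lists called in the same order numbered 5, 8, 12, 2 and 3, with the block 6, 10, 12, 4 and 6, with fry 0, 8, 10, 0 and 0, with the mean of all probe sets 6, 9, 12, 2 and 4, without the 3 arrays 4, 9, 11, 3 and 2, with low signal as a term 5, 8, 11, 2 and 5, and 0 throughout with an estimated correlation, with or without the block. By fry the cholesterol list had adjusted p = 0.139 in LH against control, 0.0535 in BMP6 against control, 0.00177 in LH+BMP6 against LH and 0.56 in the interaction. With 4 arrays per group an interaction of 0.5 was recovered in 26.9% of simulated probe sets, so its count of 0 excludes no change of that size.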

Other observations

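The splits of the arrays were planned before the results were seen, and 0 tests of this part were chosen after them.

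The 8 arrays of 2 groups can be split into 4 and 4 in 35 ways. In BMP6 against control the real split gave 4340 calls, the only 1 of 35 with as many, and the highest of the others gave 1. In LH+BMP6 against LH it gave 4879, again 1 of 35, and the highest other gave 23. For both, 1 of 35 lies under 1 in 20 and is the smallest share these splits can give. The 35 include splits that do not part the pairs of the same replicate number. Of the 8 splits that part every pair of the same replicate number, 1 gave as many calls in each comparison and the highest other gave 0, but 8 splits are too few for a share under 1 in 20. In LH against control 2 of 35 splits gave at least the real 3 calls, and the highest other gave 29, so among the 35 chance cannot be excluded. Of the 8 that part every pair 1 gave as many, the highest other gave 0, and 8 are again too few. The split with 29 calls parts 0 pairs and set replicates 1 and 2 of both groups against replicates 3 and 4, which may reflect the batches of ovaries, and with the replicate block 2 probe sets were called, SCG2 at adjusted p = 0.000878. In LH+BMP6 against BMP6 the real split gave 0 calls, 35 of 35 splits had as many, and the highest other, again replicates 1 and 2 against 3 and 4, gave 8, with 0 called under the replicate block. Of its 8 splits that part every pair 8 had as many, and the highest other gave 0. In the interaction 100 of 100 draws had at least the real 0 calls, and the highest other gave 29. Any split or draw has at least 0 calls. The shares with as many calls in LH+BMP6 against BMP6 and in the interaction were therefore fixed in advance and decide nothing.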
